A study of Rattus norvegicus with 6 samples.

How the data were processed

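The series holds 6 samples, each a pairing of 2 of the 4 rat groups described in the report, with both channels carrying RNA of a group and no common reference. Per the labels' protocols, the region of the fracture was frozen and milled, total RNA was isolated with Trizol, and amplified antisense RNA was coupled to Cy3 or Cy5. Per the labels, both dyes are listed for both channels, and the series design gives each pairing a dye-swap array, so each deposited column appears to combine 2 arrays. The labels do not say that the 3 numbered samples of a group are separate rats, so p-values measure the spread between these samples, part of which may be technical.

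The deposited values are log ratios, 1 per probe and pairing, and were used as deposited. Their log base and their numerator are not given in the sources used here, nor are the scanner, the background correction, the normalization and the filters. The values show that every deposited column was centred on its mean before deposit, since the means are 0 to within rounding, and that none of the columns has a missing value. Column medians were -0.004736 for pair-fed fracture against pair-fed no fracture, 0.01759 for pair-fed fracture against alcohol-fed fracture, -0.04814 for pair-fed fracture against alcohol-fed no fracture, 0.006055 for pair-fed no fracture against alcohol-fed fracture, 0.01767 for pair-fed no fracture against alcohol-fed no fracture and 0.0234 for alcohol-fed fracture against alcohol-fed no fracture. Signal over background is not used here, so dim probes could not be left out. Because values are centred within each column, a shift common to all genes cannot be seen.

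Of 26503 probes, 22 control spots (10 of them named Alien and 12 named as rat controls) were left out and 26481 were tested. The platform annotation gave 1 symbol to 15521 probes and none to 10960. Through a table of current rat symbols, 11824 of these symbols were current, 3638 were updated through a synonym and 59 were kept as annotated. Probes of one gene were averaged, which joined the probes of 2219 genes and left 23549 rows, 12589 of them named genes. Rows without a symbol stayed in the tests and are not named.

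The main model was a limma 3.58.1 fit (R 4.3.3) to all 6 pairings, in which each pairing had +1 for its first-named and -1 for its second-named group. The fit has 3 residual degrees of freedom, to which the moderated variance added 3.66 prior degrees of freedom with a prior standard deviation of 0.258. Each comparison thus uses the direct pairing and the paths through the other groups. The contrasts were the effect of alcohol in fractured and in unfractured rats, the effect of fracture on each diet, the interaction and the average fracture effect. Tests were two-sided, with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists within a contrast, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. The lists were early callus matrix, inflammatory cytokines, neutrophil, macrophage, osteoblast and bone matrix, chondrocyte, osteoclast, BMP and TGF-beta signalling, Wnt signalling, endothelium with angiogenesis and hypoxia, erythroid, B lymphocyte, T and NK cell, skeletal muscle, smooth muscle and pericyte, adipocyte, ethanol metabolism and oxidative stress, proliferation and interferon response. Lists, contrasts, alternatives and the rule for named genes were fixed before the data were examined.

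The rule for named genes took, per contrast, the 8 largest positive and 8 largest negative fitted values among rows past the threshold with 1 symbol and the same sign on the direct pairing. For the average fracture effect it required the same sign on all 4 pairings of a fractured with an unfractured group. Where fewer than 8 passed in a direction, it took those that passed and, up to 5 in all, the largest with an unadjusted p under 0.01, and provisional locus symbols were skipped. It added up to 4 members with the smallest p of each list described, and Bmp2, Vegfa, Il6, Tnf, Il1b, Runx2, Sp7, Bglap, Adh1 and Aldh2 (Adh1 is not analysed here). Klf1, Gata1 and the single called members of other lists, and gene families and clock genes outside the lists, were chosen after their values were seen.

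The direction check compared the residual sum of squares of the fit under all 32 distinct sign patterns of the 6 columns, and the pattern of the titles ranked 7. The check of the overall sign did not say in advance whether lists are compared by median or by mean, and both are given. The model was tested on simulated data of 23549 rows. For the effect of alcohol in fractured rats, 27% of 100 rows changed by 1 log unit and 76% of 100 rows changed by 2 units were recovered. For the effect of fracture in alcohol-fed rats these shares were 27% and 78%. With no effect present 0 rows were called in each of the 6 contrasts. The simulated noise was independent between genes and had, for each gene, the same spread on every pairing. The deposited columns differ in spread and genes may be correlated, so these figures do not give the error rate or the recovery in the real data. Alternatives were median-centred pairings, pairings scaled to 1 spread, single probes, a robust prior, no moderation, array weights, each pairing left out in turn, a minimum of 1.5-fold under an assumed base of 2, and an additive model. Turned columns and the removal of rows with an exact 0 were added after seeing the data. Chance was examined by refitting under 48 regroupings that exchange fracture labels within a diet, or diet labels within a fracture state, and keep the complete set of pairings.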

Results

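Gene expression was measured on 2-colour oligonucleotide arrays in tissue from the right hind-limb of Sprague-Dawley rats. Weanling rats of 4 weeks were kept on a liquid diet with ethanol, or pair-fed a matched diet without it, for 4 weeks. Part of the rats on each diet then received a pinned, closed fracture in the middle of the bone shaft, and tissue was taken after 3 days, in the inflammatory stage of healing. The 4 animal groups were pair-fed with fracture, pair-fed without fracture, alcohol-fed with fracture and alcohol-fed without fracture, with 3 numbered samples in each. Every possible pairing of groups was hybridised, so there were 6 pairings and 12 arrays including the dye swaps, and each numbered sample was used on 1 pairing only. Each pairing gave 1 deposited log ratio per probe. The spread of these ratios differed between pairings, with standard deviations over probes from 0.2516 for pair-fed fracture against pair-fed no fracture to 0.5724 for the corresponding alcohol-fed pairing. The small number of arrays limits the precision of every value.

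All values are in log-ratio units whose base is not given in the sources used here, so no folds are quoted, and each fitted value is given ± its standard error. Each deposited ratio is read as first-named over second-named group of its title, which is an assumption that neither the dyes nor the data settle. On this reading a positive difference lies towards the alcohol-fed or the fractured group. The check set beforehand asked whether early callus matrix genes lay above erythroid and B lymphocyte genes after fracture. Their medians in the average fracture effect were 0.003, 0.012 and -0.15, so the early callus matrix genes lay above the B lymphocyte genes only. By means, which the check had not chosen between, they lay above both (0.057 against -0.139 and -0.233), and the direction is not called likely. With the column of pair-fed fracture against alcohol-fed no fracture turned, the medians were 0.06, -0.44 and -0.13, so the check would be met by medians too. If all deposited ratios ran the other way, every sign below would turn together and the sizes and counts would stay. If single columns ran the other way, the comparisons themselves would change. The ratios of pair-fed fracture against alcohol-fed fracture and of pair-fed fracture against alcohol-fed no fracture had a correlation across probes of -0.616, although both share a group. Group differences fitted with the titles' signs left 0.403 of the sum of squares unexplained, where 0.5 would be left with no group differences, and turning the column of pair-fed fracture against alcohol-fed no fracture left 0.317. That turn was tried only after the data had been seen, and it is not the one used for the values below.

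The focus of the series was the effect of alcohol within fractured rats. Among named genes with an unadjusted p under 0.01, the largest positive values belonged to Mustn1, a nuclear protein of muscle and skeletal repair, at 2.60 ± 0.42, Kdf1 at 2.54 ± 0.28, the ubiquitin hydrolase Uchl1 at 2.14 ± 0.39, the endocytic adaptor Eps15 at 2.07 ± 0.22 and Ccl7, a monocyte-attracting chemokine, at 2.02 ± 0.27. By the same rule the largest negative values belonged to Alas2, which starts haem synthesis in red cell precursors, at -2.45 ± 0.37, Zbtb18 at -2.05 ± 0.29, the circadian transcription factor Dbp at -1.91 ± 0.23, perforin Prf1 at -1.83 ± 0.40 and the neutrophil enzyme Mpo at -1.77 ± 0.37. The rule required these 10 genes to have the same sign on the pairing of both groups with each other. Taken as alcohol-fed over pair-fed, their values on that pairing ran from 3.36 for Mustn1 to -3.33 for Alas2. No gene passed the threshold. Of 23549 rows tested with limma, 0 had an adjusted p under 0.05, the smallest adjusted p was 0.103, and 2712 had an unadjusted p under 0.05 where chance would give about 1177 if rows were independent, and 8 of 48 regroupings of the diet labels, the real one included, gave as many. With the column of pair-fed fracture against alcohol-fed no fracture turned, 435 genes passed, and the values of these 10 genes ran from 3.06 ± 0.37 for Mustn1 to -2.54 ± 0.33 for Alas2, with all but Mpo (limma adjusted p = 0.0507) past the threshold. Without moderated variances 4 passed, and array weights, whose fit did not converge, gave 580.

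By camera with its preset correlation, 3 of the 19 fixed gene lists were shifted in that comparison. Skeletal muscle markers had a median of 0.76, with 14 of 16 measured members positive (adjusted p = 0.000128). Among the members with the smallest p, the fast troponin Tnni2 was at 1.67 ± 0.34, the glycogen phosphorylase Pygm at 2.01 ± 0.43 and the myosin-binding protein Mybpc2 at 1.07 ± 0.24, while the muscle enolase Eno3 was at -0.86 ± 0.21. Adjusted over the list alone, 5 muscle members passed on the positive side and 1 on the negative side. Erythroid markers had a median of -0.50, and 3 of 14 members were positive (adjusted p = 0.000128). The haemoglobin chaperone Ahsp at -1.62 ± 0.20, the mitochondrial iron importer Slc25a37 at -1.08 ± 0.15 and ferrochelatase Fech at -1.09 ± 0.27 lay with Alas2, and 5 members passed on the negative side when adjusted over the list alone. Proliferation genes had a median of -0.24, and 5 of 19 were positive (adjusted p = 0.0019). Cdc20 was at -1.06 ± 0.15, Mki67 at -1.39 ± 0.21, Mcm7 at -0.79 ± 0.17 and Ccna2 at -0.80 ± 0.27, and 3 members passed on the negative side when adjusted over the list alone. These calls were lost with an estimated correlation, where the adjusted p was 0.424 for muscle, 0.292 for erythroid and 0.292 for proliferation. The loss does not show that genes of each list are correlated. For proliferation the estimate was -0.022, below the preset 0.01, yet the unadjusted camera p rose from 3e-04 to 0.0294. This setting thus changes more than the correlation. The erythroid and proliferation calls were also lost with the column of pair-fed fracture against alcohol-fed no fracture turned. There the medians moved to -0.16 and 0 (camera adjusted p = 0.0897 and 0.138), while muscle kept its call (median 1.00, adjusted p = 6.97e-05).

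The remaining lists did not pass in fractured rats. Inflammatory cytokines had a median of 0.10, and their members with the smallest p lay on both sides, with Ccl7 joined by Il18 at 1.47 ± 0.42 and Ccl3 at 1.41 ± 0.43 and opposed by Ccl4 at -1.11 ± 0.24. Neutrophil markers had a median of -0.22 (camera adjusted p = 0.0693), and S100a9, a calcium-binding protein abundant in neutrophils, was at -1.02 ± 0.22. Macrophage markers had a median of 0.04, B lymphocyte markers of -0.23 and T and NK cell markers of -0.09. The early callus matrix list had a median of 0.14, osteoblast and bone matrix genes of -0.02, chondrocyte markers of -0.14 and osteoclast markers of 0.09, the last with a mean of -0.26. The median was 0.05 for BMP and TGF-beta signalling, whose mean was -0.06, and -0.02 for Wnt signalling. Endothelium, angiogenesis and hypoxia genes had a median of -0.09, smooth muscle and pericyte markers of 0.06, adipocyte markers of 0.18, ethanol metabolism and oxidative stress genes of 0.08 and interferon response genes of 0.02. With the column of pair-fed fracture against alcohol-fed no fracture turned, none of these lists passed, but several medians moved. Among them were early callus matrix at 0.05, osteoclast at -0.02, adipocyte at 0.02, B lymphocyte at -0.04, chondrocyte at -0.23 and ethanol metabolism at 0.23. Of the genes fixed in advance, Bmp2, a growth factor of bone repair, was at -0.39 ± 0.21, Vegfa at -0.33 ± 0.14, Il6 at -0.22 ± 0.15, Tnf at 0.14 ± 0.18 and Il1b at 0.14 ± 0.19. The osteoblast genes Runx2, Sp7 and Bglap were at -0.16 ± 0.16, 0.14 ± 0.20 and 0.35 ± 0.25, and the acetaldehyde-oxidising enzyme Aldh2 was at -0.20 ± 0.23. For these 9 genes the limma adjusted p lay between 0.433 and 0.855. Turning the column of pair-fed fracture against alcohol-fed no fracture put Bmp2 at -0.08 ± 0.16, Il6 at -0.43 ± 0.16, Sp7 at 0.28 ± 0.16 and Tnf, with its sign changed, at -0.02 ± 0.13, and none of the 9 passed.

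The comparison of fracture with no fracture in alcohol-fed rats was the one with genes past the threshold. Among named genes past it, the largest positive values belonged to Kdf1 at 3.35 ± 0.28, Mustn1 at 2.92 ± 0.42, Eps15 at 2.56 ± 0.22, Ccl7 at 2.47 ± 0.27, Uchl1 at 2.44 ± 0.39, the splicing factor Crnkl1 at 2.18 ± 0.29, Tnni2 at 2.08 ± 0.34 and the sarcomere protein Actn2 at 2.01 ± 0.39. By the same rule the largest negative values belonged to Alas2 at -2.17 ± 0.37, the histone gene Hist1h2bo at -2.06 ± 0.28, C1qtnf4 at -2.05 ± 0.25, the secreted factor Metrnl at -2.05 ± 0.35, the kinase Pkn2 at -2.05 ± 0.25, the mitochondrial ribosomal protein Mrpl19 at -2.02 ± 0.27, Ints5 at -1.99 ± 0.35 and the serotonin receptor Htr1f at -1.97 ± 0.36. Copies of histone genes are nearly identical in sequence, so the copy named for a histone probe is uncertain. Limma called 999 of 23549 rows, 195 positive and 804 negative, with a smallest adjusted p of 0.028, and for the 16 named genes the adjusted p lay between 0.028 and 0.0447. The median of the called rows was 1.12 on the positive side and -1.26 on the negative side. All 999 had the sign of the fit on each of the 3 pairings that held alcohol-fed fracture samples. These pairings enter the fitted value with that sign, and the rows were chosen on that value, so this is not separate support. The call rested on few arrays and on the signs of the columns. The count was 0 without the pairing of pair-fed fracture and pair-fed no fracture, 0 without that of pair-fed fracture and alcohol-fed no fracture, 0 without the direct pairing, and 655 without that of pair-fed no fracture and alcohol-fed fracture. It was also 0 with all pairings scaled to 1 spread, 0 with the column of pair-fed fracture against alcohol-fed no fracture turned, and 2 without moderated variances. With that column turned Kdf1 was at 2.84 ± 0.40, Mustn1 at 2.46 ± 0.37, Alas2 at -2.08 ± 0.33 and Hist1h2bo at -1.52 ± 0.39, with a limma adjusted p of 0.0658, 0.0667, 0.0715 and 0.146.

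Among the lists in alcohol-fed rats, skeletal muscle markers had a median of 0.91 with 14 of 16 members positive (camera adjusted p = 0.00092). Of these members 3 passed as positive, Mybpc2 at 1.73 ± 0.24 with Tnni2 and Actn2, 1 passed as negative, Eno3 at -1.18 ± 0.21, and 12 did not pass. Adjusted over the list alone, 8 passed as positive and 1 as negative. Erythroid markers had a median of -0.33 (camera adjusted p = 0.03), and 4 of 14 passed, all negative, which were Ahsp at -1.75 ± 0.20, Slc25a37 at -1.11 ± 0.15, Fech at -1.67 ± 0.27 and Alas2. Other erythroid members did not pass, and the transcription factors Klf1 and Gata1 were at 0.27 ± 0.24 and 0.06 ± 0.28. Proliferation genes had a median of -0.18 (camera adjusted p = 0.033), and 3 of 19 passed, which were the proliferation antigen Mki67 at -1.60 ± 0.21, the mitotic activator Cdc20 at -0.98 ± 0.15 and the replication helicase subunit Mcm7 at -0.98 ± 0.17. With an estimated correlation the adjusted p was 0.461 for each of these lists, and fry passed other lists, the macrophage, smooth muscle and ethanol metabolism lists (adjusted p = 0.0299 each). With the column of pair-fed fracture against alcohol-fed no fracture turned, the camera shifts were larger for erythroid markers (median -0.75, adjusted p = 1.68e-05) and proliferation genes (-0.40, 0.000609), muscle was at 0.72 (0.00305), and B lymphocyte markers passed as well (-0.51, 0.0482). Inflammatory cytokines were not shifted as a list (camera adjusted p = 0.572). Ccl7 passed as positive, while the cytokine Lif at -0.81 ± 0.16 and the chemokine Ccl4 at -1.14 ± 0.24 passed as negative. Among macrophage markers, the lysozyme Lyz2 at 0.81 ± 0.15 and the endotoxin co-receptor Cd14 at 0.99 ± 0.20 passed as positive and 15 of 17 did not pass. Of the neutrophil markers S100a9 passed at -1.68 ± 0.22, with 13 of 14 not passing. The smooth muscle gene Tagln passed at 1.65 ± 0.26. The other members past the threshold were Col6a3 at 1.88 ± 0.35 in the early callus matrix list, Col1a2 at -0.90 ± 0.18 in the osteoblast list, Matn1 at -1.19 ± 0.16 in the chondrocyte list and Dkk3 at -0.91 ± 0.16 in the Wnt list. Hmox1 passed at -0.78 ± 0.16 in both the endothelium and the ethanol metabolism list, and in the interferon list Gbp2 passed at -0.73 ± 0.14 and Mx1 at 1.01 ± 0.20. None of the list members named here passed with the turned column, which put Col6a3 at 1.09 ± 0.50 (limma adjusted p = 0.314) and Lif at -0.53 ± 0.23 (0.294). None of the genes fixed in advance passed, with Vegfa at -0.41 ± 0.14, Il6 at -0.48 ± 0.15 and Bmp2 at -0.15 ± 0.21. The turned column put these at -0.37 ± 0.13, -0.27 ± 0.16 and -0.46 ± 0.16, so Bmp2 and Il6 change places.

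**Figure D1:**
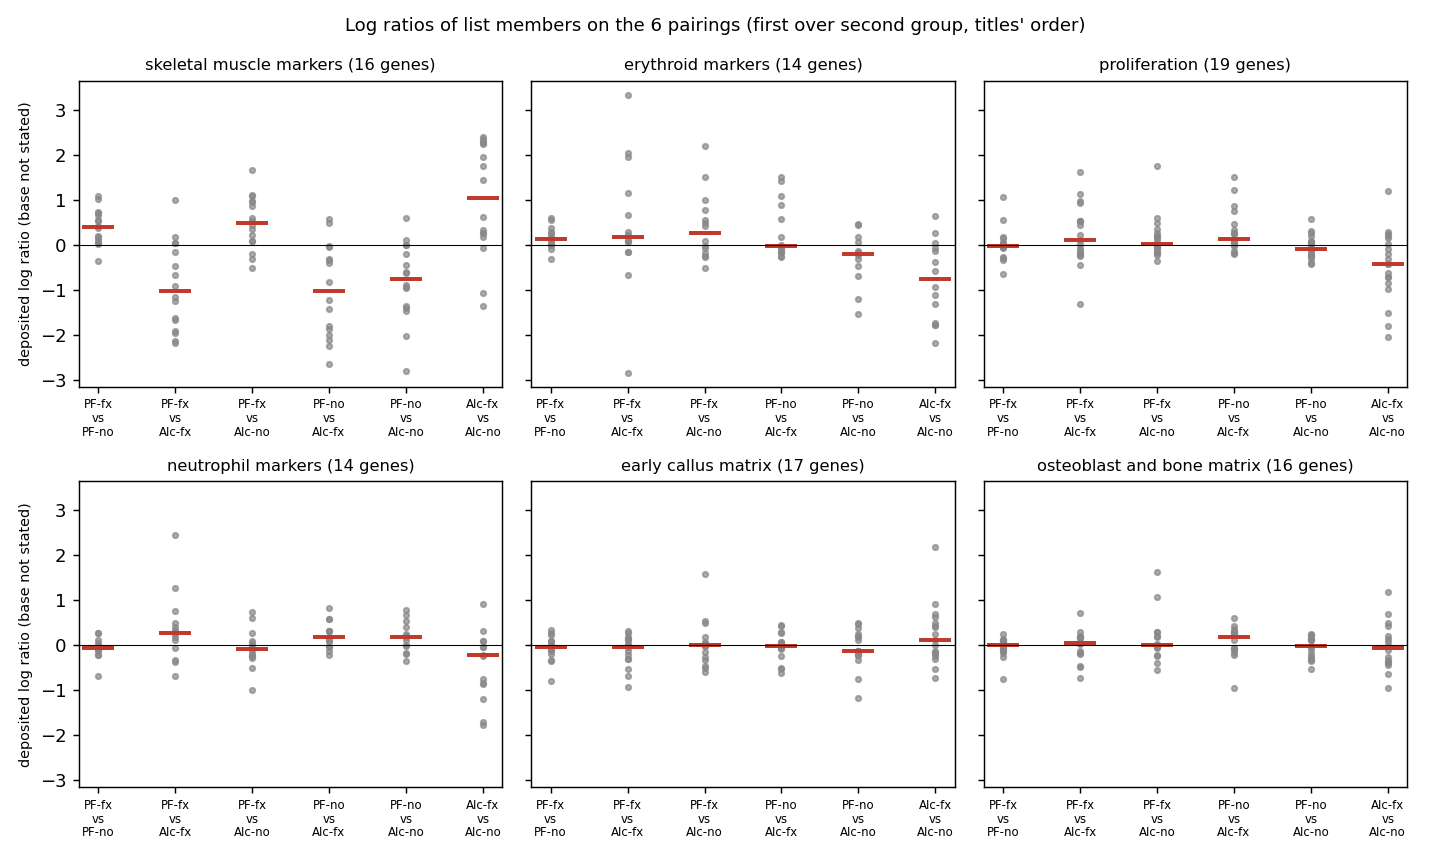
Deposited log ratios (vertical axis, base not stated) of the members of 6 gene lists on each of the 6 pairings (horizontal axis; PF, pair-fed; Alc, alcohol-fed; fx, fracture; no, no fracture), with 1 grey point per gene and a red bar at the median. The skeletal muscle medians were -1.04, -1.03 and 1.03 on the 3 pairings that held alcohol-fed fracture samples, and the erythroid medians on the same pairings were 0.16, -0.03 and -0.76.

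In pair-fed rats the fracture comparison had values on a smaller scale. With the titles' signs, the standard deviation over genes was 0.209, against 0.456 in alcohol-fed rats. Among named genes with an unadjusted p under 0.01, the largest positive values were those of Mrpl37 at 1.33 ± 0.34, the matrix protein Aspn at 1.30 ± 0.35, the fast muscle myosin light chain Myl11 at 1.27 ± 0.22, Nhlh2 at 1.22 ± 0.32 and the muscle cytochrome oxidase subunit Cox6a2 at 0.99 ± 0.26. By the same rule the negative ones were Cul5 at -0.87 ± 0.23, the B cell surface protein Cd72 at -0.80 ± 0.14, Sart1 at -0.80 ± 0.18, Bcat2 at -0.77 ± 0.21 and Ncbp1 at -0.75 ± 0.18. This order rests on the titles' signs, since turning the column of pair-fed fracture against alcohol-fed no fracture put Mrpl37 at 0.89 ± 0.24, Aspn at 0.45 ± 0.42, Myl11 at 0.91 ± 0.24, Nhlh2 at 0.48 ± 0.55 and Sart1 at -0.53 ± 0.24. None of these genes passed. Limma called 0 rows, the smallest adjusted p was 1, and 447 rows had an unadjusted p under 0.05, fewer than the 1177 that chance would give. Without moderated variances 0 passed as well. All pairings weighed alike in the fit, although standard deviations ran from 0.2516 on the direct pairing here to 0.5724 on the alcohol-fed one. A gene's SE was therefore the same on both diets. With pairings scaled to 1 spread, 1379 rows had an unadjusted p under 0.05 here and 3252 in alcohol-fed rats, where 0 passed. The count below chance thus depends on the scale of the columns, and the counts do not show a weaker response in pair-fed rats. Skeletal muscle markers had a median of 0.65 with 14 of 16 positive (camera adjusted p = 5.76e-07), including Mybpc2 at 0.85 ± 0.24, Tnni2 at 1.04 ± 0.34, Ckm at 1.12 ± 0.37 and Myh7 at 0.89 ± 0.32. Erythroid markers had a median of 0.24 with 13 of 14 positive (camera adjusted p = 0.00262), among them the blood group protein Ermap at 0.48 ± 0.15 and Rhag at 0.70 ± 0.43. With an estimated correlation the adjusted p was 0.489 for both lists. With the column of pair-fed fracture against alcohol-fed no fracture turned the medians were 0.26 for muscle and 0.17 for erythroid markers (camera adjusted p = 0.0703 and 0.442). Of the genes fixed in advance, Bmp2 was at 0.13 ± 0.21, Vegfa at 0.09 ± 0.14, Il6 at 0.06 ± 0.15 and Il1b at 0.01 ± 0.19.

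Without fracture, alcohol-fed and pair-fed rats were compared in the same way. Among named genes with an unadjusted p under 0.01, the largest positive values belonged to the olfactory receptor genes Olr1493 at 1.62 ± 0.40, Or1e21b at 1.34 ± 0.37 and Or5ap2b at 0.89 ± 0.20, to Morc3 at 1.37 ± 0.23 and to the transcription factor Tfec at 0.90 ± 0.19. By the same rule the largest negative values belonged to Krtcap2 at -1.01 ± 0.25, Taf7l at -0.92 ± 0.22, Plekhh1 at -0.90 ± 0.24, the membrane adaptor Ank2 at -0.88 ± 0.16 and Sall1 at -0.84 ± 0.14. Here too the order rests on the titles' signs, and the same turn put Olr1493 at 1.11 ± 0.68, Or1e21b at 1.21 ± 0.46, Krtcap2 at -0.77 ± 0.36, Taf7l at -0.45 ± 0.43 and Plekhh1 at -0.84 ± 0.26. None of these genes passed. Limma called 0 rows, with a smallest adjusted p of 0.999, and 819 rows had an unadjusted p under 0.05 against 1177 by chance, while without moderated variances 0 passed. Skeletal muscle markers had a median of 0.23 with 14 of 16 positive (camera adjusted p = 0.0127, or 0.843 with an estimated correlation), led by Myh7 at 1.08 ± 0.32, Pygm at 1.05 ± 0.43 and Acta1 at 1.18 ± 0.69. This call was lost without the direct pairing, where the sign of the shift also turned (adjusted p = 0.77). With the column of pair-fed fracture against alcohol-fed no fracture turned it was larger, with a median of 0.72 (adjusted p = 6.66e-06), and erythroid markers passed as well (0.30, 0.000203). Macrophage markers had a median of -0.16 (camera adjusted p = 0.127), with Lyz2 at -0.42 ± 0.15 and Tyrobp at -0.44 ± 0.18.

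Whether the fracture response itself differed between diets was tested as an interaction. Among named genes with an unadjusted p under 0.01, Kdf1 at 3.44 ± 0.39, Mustn1 at 2.57 ± 0.60, Ccl7 at 2.38 ± 0.38, Crnkl1 at 2.33 ± 0.41 and Eps15 at 2.25 ± 0.31 were the most positive. Alas2 at -2.66 ± 0.52, Zbtb18 at -2.44 ± 0.41, Ints5 at -2.38 ± 0.49, Mrpl19 at -2.38 ± 0.38 and C1qtnf4 at -2.38 ± 0.35 were the most negative. No gene passed, since limma called 0 rows with a smallest adjusted p of 0.138, and 2492 rows had an unadjusted p under 0.05. Without moderated variances 2 passed. The 999 genes called in alcohol-fed rats are therefore not shown, gene by gene, to respond differently from pair-fed rats, and their median in pair-fed rats, taken in the direction of the alcohol-fed value, was 0.00. Of these genes 949 had an unadjusted limma interaction p under 0.05. They were chosen on the alcohol-fed difference, which is part of the interaction, so this count is not separate support. Erythroid markers differed as a list, with a median interaction of -0.67 and 3 of 14 members positive (camera adjusted p = 9.46e-05), and so did proliferation genes with a median of -0.27 and 4 of 19 positive (camera adjusted p = 0.0173). With an estimated correlation the adjusted p was 0.407 for both, and with the turned column, which leaves these medians unchanged, it was 1.18e-05 and 0.0101 at the preset correlation. Ahsp was at -1.94 ± 0.29, Fech at -1.78 ± 0.38 and Mki67 at -1.35 ± 0.29. Skeletal muscle markers did not pass, with a median of 0.41 (camera adjusted p = 0.268). Across all 23549 rows the fracture responses on the 2 diets had a Pearson r of 0.178 and a Spearman rho of 0.114. This is a correlation across genes, which are not independent replicates, and it was -0.134 with the column of pair-fed fracture against alcohol-fed no fracture turned.

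**Figure D2:**
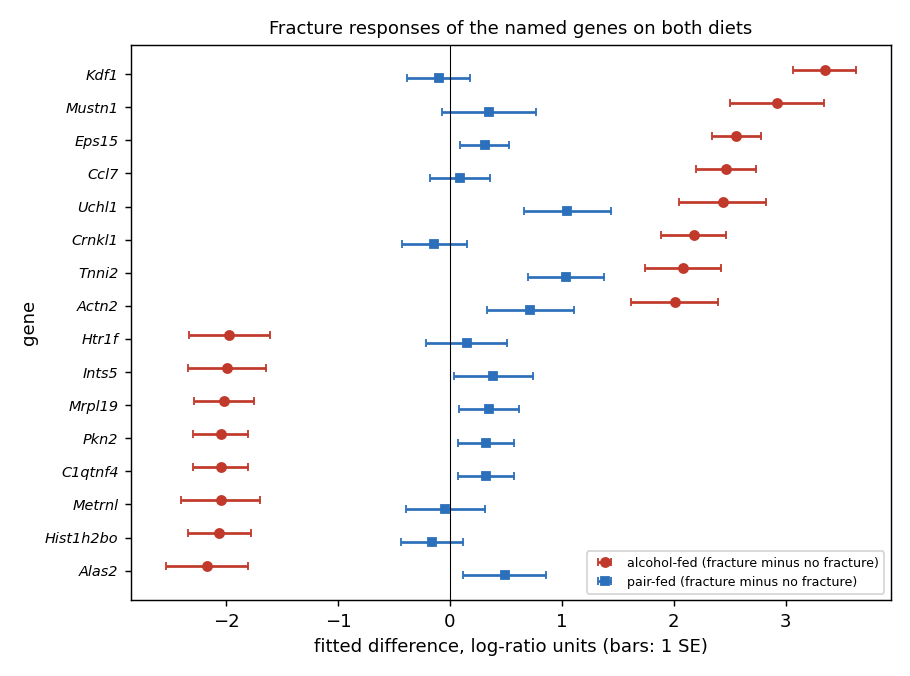
Fitted difference between fracture and no fracture (horizontal axis, log-ratio units, each ratio read as first-named over second-named group, bars 1 SE) for the 16 genes named in alcohol-fed rats (vertical axis), in alcohol-fed rats (red circles) and in pair-fed rats (blue squares). The alcohol-fed values run from -2.17 for Alas2 to 3.35 for Kdf1, and Uchl1 is at 2.44 in alcohol-fed and 1.05 in pair-fed rats.

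Averaged over both diets, and among named genes with an unadjusted p under 0.01 and 1 sign on all 4 pairings of a fractured with an unfractured group, the fracture effect was largest for the skeletal muscle actin Acta1 at 1.80 ± 0.49, Uchl1 at 1.74 ± 0.28, Mustn1 at 1.64 ± 0.30, Zfp330 at 1.61 ± 0.36 and the small GTPase Rhob at 1.60 ± 0.38. On the negative side were Vpreb3, a gene of developing B cells, at -1.07 ± 0.27, Metrnl at -1.05 ± 0.25, the haem-regulated kinase Eif2ak1 at -1.01 ± 0.23, Mr1 at -0.98 ± 0.22 and the cytokine Il4 at -0.97 ± 0.13. With the column of pair-fed fracture against alcohol-fed no fracture turned, which ends the condition of 1 sign, Acta1 was at 0.97, Uchl1 at 1.16, Mustn1 at 1.18, Zfp330 at 0.77 and Rhob at 0.54, and the negative genes lay between -0.53 and -0.70. None of these genes passed. Limma called 0 rows with a smallest adjusted p of 0.157, and 3195 rows had an unadjusted p under 0.05. Without moderated variances 1 passed. Skeletal muscle markers had a median of 0.76 with 14 of 16 positive (camera adjusted p = 2.78e-06, or 0.574 with an estimated correlation). Mybpc2 at 1.29 ± 0.17, Tnni2 at 1.56 ± 0.24, Ckm at 1.45 ± 0.26 and Actn2 at 1.36 ± 0.28 had the smallest p, and 8 members passed as positive and 1 as negative when adjusted over the list alone. By camera with that column turned, muscle markers were at 0.72 (camera adjusted p = 0.000129), and erythroid markers (-0.44, 0.000129) and proliferation genes (-0.19, 0.000174) passed as well.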

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

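The interaction tests were planned, while the tests of explanations in this part, the regroupings included, were written down after the values they concern had been seen.

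The fracture response of erythroid markers differed between the diets by the interaction test (camera adjusted p = 9.46e-05), with a median of 0.24 in pair-fed and -0.33 in alcohol-fed rats. A lower share of marrow in the alcohol-fed fracture samples may account for it. Neutrophil and B lymphocyte markers, which also come from marrow, had median interactions of -0.06 and -0.09 against -0.67 for erythroid markers. Their means were -0.28 and -0.42 against -0.84. A permutation test of the difference in means between erythroid and these 2 lists, over genes, gave p = 0.068. A lower marrow share and a change of erythroid cells alone therefore cannot be told apart with lists of this size. The biological reading, that diet altered the erythroid response to fracture, is untested beyond the interaction, which did not pass with an estimated correlation (adjusted p = 0.407) or with fry (adjusted p = 0.132).

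The fracture response of proliferation genes also differed between the diets by the interaction test, with a camera adjusted p of 0.0173 and a median of 0.01 in pair-fed and -0.18 in alcohol-fed rats. It did not pass with an estimated correlation (adjusted p = 0.407) or with fry (adjusted p = 0.132). Erythroid markers lay on the same side with a larger median interaction of -0.67, and no explanation of the proliferation shift was tested.

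The 999 genes called for fracture in alcohol-fed rats could come from several sources. Other arrangements of the fracture labels gave as many calls in 6 of 48 regroupings, the real one included, with 1566 as the highest of the others, so chance is not excluded. The arrays of the direct pairing were examined as the whole source. Of the 999 genes largest on that pairing alone, 92.2% had the same sign in the fit of the other 5 pairings, where their median was 1.06. This cannot exclude that source, since genes move together and may share a sign by chance. The first component of the 6 columns held 49.1% of the sum of squares. The fit of the other 5 pairings also uses the column of pair-fed fracture against alcohol-fed no fracture, whose sign is open. A larger share of muscle in the alcohol-fed fracture samples was examined with the erythroid and macrophage lists, which moved apart. Their means were -0.56 and 0.12 (permutation p of the difference in means = 0.021 over genes, which are not independent). This cannot decide the question, since the tissue that muscle would displace need not hold both cell types alike. Calls of both signs stay open to it.

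For the other comparisons the regroupings do not bear on the counts past the threshold, since these were 0 and 48 of 48 regroupings gave at least that many. The highest other count was 0 for both effects of alcohol and for fracture in pair-fed rats, and 837 for the interaction and for the average fracture effect. The count of 837 is the highest over the other regroupings, so it may arise by chance, and its source was not tested. Rows with an unadjusted p under 0.05 were as many as in the real arrangement in 8 of 48 regroupings for alcohol in fractured rats (2712, highest other 3352), 22 for alcohol in unfractured rats (819, 2614) and 18 for fracture in pair-fed rats (447, 1689). They were as many in 8 for the interaction (2492, 4506) and 5 for average fracture (3195, 4506), so chance is not excluded for any of these counts.

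A control spot outside the comparisons, Rn_Control_07, had a log ratio of 1.94 on pair-fed fracture against alcohol-fed no fracture and of -1.59 on pair-fed fracture against alcohol-fed fracture, while the 10 Alien spots stayed within 0.27 and the 11 other rat control spots within 0.66 of 0.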

How the results depend on the processing

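Turned columns and rows without exact 0 were chosen after seeing the data, and the cause of a change was not tested unless stated. No paired analysis was possible because each numbered sample is on 1 pairing. No value was missing, so the alternative for missing values gives nothing, and neither does the correlation over genes past the average fracture threshold, which 0 genes passed. Leaving out 1 pairing leaves 2 residual degrees of freedom. The 999 genes for fracture in alcohol-fed rats became 0 with pairings scaled to 1 spread, 2 without moderation, 0 with the best-closing sign pattern, 0 with pair-fed fracture against alcohol-fed no fracture turned, and 0 to 918 with 1 pairing left out. Median-centring gave 1004 with 962 of the 999 among them, and array weights 1098. The comparisons with 0 genes stayed at 0 with any pairing left out, centred, scaled, by single probes, with a robust prior and without exact 0. Without moderation alcohol in fractured rats gave 4, the interaction 2 and average fracture 1. Array weights, whose fit did not converge and gave 1 pairing a weight of 54.06, gave 580 for alcohol in fractured rats, 15940 for fracture in pair-fed rats, 1781 for the interaction and 1504 for average fracture. The best-closing signs gave 1213 for alcohol in fractured rats and 4 for fracture in pair-fed rats, and the turned column 435 for alcohol in fractured rats. The additive model called 0 genes for fracture and 0 for alcohol.

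With an estimated correlation 0 lists passed in each of the 6 contrasts, and with fry 0 in each except fracture in alcohol-fed rats, where it gave 3, none of them among the 3 by camera. The camera p of the proliferation list rose although its estimated correlation lay below the preset one. Correlation alone therefore does not account for the lists lost with that setting. With 1 pairing left out the lists past the threshold numbered 2 to 4 for alcohol in fractured rats (3 with all pairings), 1 to 3 for fracture in pair-fed rats (2), 1 to 4 for fracture in alcohol-fed rats (3), 0 to 2 for alcohol in unfractured rats (1), 1 to 2 for the interaction (2) and 1 to 4 for average fracture (1). With the turned column they were 1, 0, 4, 2, 2 and 3 in the same order. The muscle shift of alcohol in unfractured rats had an adjusted p from 4.14e-05 to 0.77 with 1 pairing left out, and turned its sign without the direct pairing (0.77). The correlation of the fracture responses ranged from -0.134 to 0.429 with 1 pairing left out, turning negative without pair-fed fracture against alcohol-fed fracture (-0.031) and without the pairing of both unfractured groups (-0.134), and was -0.134 with the turned column. All 37 named calls kept their sign with any pairing left out and on the direct pairing, the latter being a condition of the rule for the largest values. The former is not separate support either, since these genes passed in the full fit and each refit reuses the remaining pairings.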

Other observations

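The gene families and clock genes in this part were chosen, and tested, after the data had been seen. Histone genes of the replication-dependent clusters lay on the negative side for fracture in alcohol-fed rats, with a median of -0.99 over 11 genes and 5 of them past the threshold (camera adjusted p = 0.000685 over 7 families, 0.215 with an estimated correlation). Histone H2B genes gave most of it, with Hist1h2bo at -2.06 ± 0.28, H2bc8 at -1.83 ± 0.31 and Hist1h2bh at -1.74 ± 0.28, while in pair-fed rats the family median was -0.08. For alcohol in unfractured rats the family was positive, with a median of 0.47 and 8 of 11 above 0 (camera adjusted p = 0.0338, 0.306 with an estimated correlation). The alcohol-fed no fracture group enters both comparisons, so part of the negative value may come from it. Proliferation genes (median -0.18, camera adjusted p = 0.033) and erythroid markers (-0.33, 0.03) also lay on the negative side for fracture in alcohol-fed rats, with an adjusted p of 0.461 for both with an estimated correlation. The histone genes are near copies of each other, so their probes may not be independent. With the column of pair-fed fracture against alcohol-fed no fracture turned, which leaves 0.317 of the sum of squares, 0 genes pass for fracture in alcohol-fed rats.

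Skeletal muscle markers, whose tissue is rich in mitochondria, had a median of 0.91 for fracture in alcohol-fed rats (camera adjusted p = 0.00092, 0.461 with an estimated correlation), and 2 families of mitochondrial genes passed on the same side. Subunits of mitochondrial complex I had a median of 0.21 in that comparison, with 21 of 32 positive and 0 past the threshold (camera adjusted p = 0.0248, 0.215 with an estimated correlation). ATP synthase subunits had a median of 0.31 with 12 of 14 positive (camera adjusted p = 0.0228, 0.304 with an estimated correlation). Muscle markers were also positive for fracture in pair-fed rats (0.65) and for alcohol in unfractured rats (0.23). Complex I was at -0.02 and -0.11 there and ATP synthase at 0 and -0.15, so neither family followed muscle. For alcohol in fractured rats muscle was at 0.76, complex I at 0.14 and ATP synthase at 0.12. Both families were taken by symbol and hold genes that are not subunits, such as Ndufaf1 and Dmac2. Mitochondrial ribosomal proteins did not pass, with a median of 0.14 over 60 genes, 1 called positive and 2 called negative (camera adjusted p = 0.12), Mrpl19 at -2.02 ± 0.27 among the negative. Cytosolic ribosomal proteins had a median of 0.01 over 64 genes and olfactory receptors one of -0.01 over 838.

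The column of pair-fed fracture against alcohol-fed no fracture runs against 2 of the 4 columns that share a group with it, with an r of -0.616 to pair-fed fracture against alcohol-fed fracture and of -0.273 to the pairing of both unfractured groups, and a sign turned at deposit may be the source. With the others, the pairings within each diet, it had an r of 0.258 and 0.234, the sign that its title gives. It is not alone in this. Pair-fed fracture against alcohol-fed fracture also ran against pair-fed fracture against pair-fed no fracture (r of -0.216). The pairing of both unfractured groups also ran, weakly, against alcohol-fed fracture against alcohol-fed no fracture (r of -0.064). Each of these 2 columns thus also runs against 2 of its 4. Turning the column of pair-fed fracture against alcohol-fed no fracture alone lowered the unexplained share of the sum of squares from 0.403 to 0.317, the lowest of the 6 single turns, which ranged up to 0.661. Turning the pairing of both unfractured groups alone also lowered it, to 0.38, and to 0.361 together with pair-fed fracture against pair-fed no fracture. Turning all columns together leaves the share unchanged, so a pattern equals the one that turns the remaining columns instead. The lowest shares, 0.293 and 0.299, thus also came with this column turned. The first turned pair-fed fracture against pair-fed no fracture with it, and the second also the pairing of both unfractured groups. The titles' signs stay possible, and no test here decides between the patterns. A share below the 0.5 that no group differences would leave is no support for them. Patterns that exclude each other, such as those at 0.317 and 0.38, also lie below it. The first component of the 6 columns (49.1% of the sum of squares) has loadings of -0.59, -0.32 and 0.62 on the pairings with alcohol-fed fracture samples and 0.38 on this one. The estimate of the interaction does not use this column.

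Dbp, a clock output gene, was at -1.81 ± 0.23 for fracture in alcohol-fed rats and past the threshold (limma adjusted p = 0.028), and at 0.16 ± 0.23 in pair-fed rats. A different time of day at collection is a candidate explanation, which would move other clock genes too. The median of Per1, Per2, Per3, Nr1d1 and Tef was -0.22 with a median SE of 0.16, but these 5 were picked after the values were seen and lay on both sides of 0, from -0.32 for Per1 to 0.36 for Per2. Cry1, a clock gene of another phase, was at 1.18 ± 0.34 (limma adjusted p = 0.122), the largest clock value after Dbp. Time of day therefore stays open.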
